A study of Mus musculus with 79 samples.

How the data were processed

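The samples were 79 laser-captured regions of femoral bone marrow of C57BL/6 mice, an inbred strain. Per the labels' protocols, femurs were fixed in 4% paraformaldehyde, cut into 12 µm frozen sections and stained for Sca-1, endomucin and DNA. Areas averaging 14500 µm2, or roughly 250 to 300 cells, were cut out with a laser microscope, and the RNA, freed from its crosslinks and taken up in 100 µl of TRI Reagent, was made into stranded total RNA libraries with a low-input kit (version 2). Total RNA libraries keep ribosomal and unspliced RNA, which lowers the share of counts that protein-coding genes receive. The regions were grouped by the niche in the labels.

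The deposited values are raw counts per Ensembl gene, 1 file per region, which the authors made by alignment and counting. STAR 2.6.0, HTSeq 0.7.2, R 3.5.0, DESeq 1.20.0 and the mm10 build are named per the submitters' processing notes, without their roles. Whether strand was used in counting is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and counts of pseudogenes and near-identical copies are uncertain. Each file holds 38561 gene identifiers, of which 36639 were matched to a symbol of GENCODE M21, the source of all coordinates, and 95 spike-in identifiers with 0 counts. Summary lines that name no gene were left out of library sizes and tests. They put 54.3% ± 10.5 (SD, n = 74) of uniquely placed reads in no gene, called outside exons here. Of all their entries for aligned reads, 67.8% ± 8.21 stood in the line for reads placed at several positions. Unaligned reads were left out of this share. A read placed at several positions may be entered repeatedly, so the share of reads may be lower. As the use of strand is not known, exon reads of the other strand may be among those called outside exons. A filtered count table of the authors lists 20753 genes in 74 regions, and 20511 of its genes were matched to the count files and 20505 had identical counts in every region. That table served as an alternative gene set, used in place of the filter on low counts. The rule behind it is not given in the sources used here. There were 0 per-sample columns left unused.

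The labels mark 74 regions as passing, and these entered the comparisons. Left out were 2 sub-endosteum regions marked as outliers in a principal component analysis, which were added back as an alternative, and 3 regions with insufficient reads. Total counts per passing region ran from 1056615 to 7634159 and protein-coding counts from 170020 to 4992175, so that a single count is a large step for sparse genes, and many genes had no count in most regions. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The unit of replication was the region, because the labels name no animals; p-values then measure the spread between regions, and they may be too small where regions share an animal.

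Counts were tested in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood F test (robust). Genes were kept by filterByExpr with the niche as group (minimum count 10, minimum total 15), which left 14510, and libraries were scaled by TMM, with factors from 0.255 to 3.17; the common dispersion was 2.71. All 5 niches and the slide as a fixed factor stood in one model, so that the niches shared one estimate of the spread. Each niche was set against the unweighted mean of the other 4, 3 pairs of niches were tested in the same model, and a test with 4 degrees of freedom covered all niches. Distance from the endosteum was tested as a slope per 100 units among the 28 artery regions, with slide as a factor and 1581 genes kept. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05; the standard error was the log2 fold change divided by the square root of F, and edgeR's p is never below that of the Poisson likelihood ratio, so that it can exceed what this ratio implies for sparse genes. If no gene differed and p-values were evenly spread, a share of 0.05 of the tested genes would have an unadjusted p under 0.05. CPM are counts over the library size of the tested genes times the TMM factor. Where a niche held no count of a gene, the fold was bounded with 3 counts over the whole niche; where it held 1 to 3 counts, the ratio of pooled CPM is given with an exact (Clopper-Pearson) 95% interval.

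The 29 gene lists of cell types and processes were tested with camera in limma 3.58.1 (preset correlation 0.01, at least 5 tested members), adjusted over all lists and the 5 niches, and for the pairs over all lists and the 3 pairs; camera compares a list with the other genes. It was repeated with the correlation estimated per list and with fry, which tests whether a list moves one way on balance. Named genes followed a rule: at most 15 higher and 6 lower genes per niche and 8 per direction for pairs and distance, by smallest p among genes with adjusted p under 0.05, a log2 fold change of at least 1 in size and a count in at least 50% of the regions of the higher group; up to 4 members per list; and 26 genes whatever their result. Predicted genes were counted and not named. The groups, the tests, the lists, this rule and most alternatives were fixed before the data were examined; genes outside the rule and alternatives chosen later are said to be so.

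Alternatives were DESeq2 1.42.0 (Wald and likelihood ratio tests, poscounts size factors), its size factors and TMMwsp factors within edgeR, limma-voom with slide as a random block, no filter on low counts, the authors' genes only, no slide term, counts summed per slide and niche, the 2 outlier regions added, captured area as a covariate, and hemoglobin, mitochondrial and the 10 most abundant genes left out. Each slide, and for the niche tests each region of the niche, was left out in turn. Fits without a slide filtered genes and estimated dispersions anew. Fits without a region kept the genes and dispersions of the whole fit, which the left-out region had helped to set. Some settings were chosen after the data were seen. They were the share of unique reads outside exons or the log2 number of detected coding genes as a covariate, and the removal of 2 libraries with over 80% of unique reads outside exons. The removal of the 1 passing region absent from the authors' region list was chosen then too. Data were handled with data.table (1.17.8), pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures drawn with matplotlib 3.10.9.

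The tests were checked on simulated counts with the means, dispersions and library sizes of these regions. With edgeR, planted log2 changes of 4 were found for 76% of genes in arteries, 88% in endosteum, 66% in low sinusoids, 50% in sinusoids and 58% in sub-endosteum, and of 2 for 50%, 32%, 10%, 22% and 10%; changes of -4 were found for 64%, 24%, 36%, 36% and 22%. Changes of -2 were found for 16%, 6%, 2%, 4% and 2% in the same order of niches, so falls of that size were mostly missed. Between 4 and 14 of 13410 unchanged genes were called per niche. DESeq2 called 77 to 119 of 12532 unchanged genes per niche and limma-voom 4 to 18, so that a DESeq2 count of that size is within what unchanged genes gave. DESeq2 also found more of the changes of -4 than edgeR, at 90%, 51%, 70%, 69% and 65% in the same order of niches. For the pairs, changes of 4 were found for 43% of genes in arteries against sinusoids, 39% in sinusoids against low sinusoids and 35% in endosteum against sub-endosteum. Of the genes unchanged within the pair, edgeR called 10, 6 and 5 in the same order and DESeq2 96, 92 and 98. Camera found 2 of 5 planted lists (20 members shifted by log2 1) and called 0 of 20 unchanged lists in arteries. The simulated counts held no slide effects and no correlation between genes. They thus test neither the preset correlation nor the error rates on the real regions. Exchanging niche labels within slides on the real regions, described below, gave up to 8 lists and up to 276 genes in a niche.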

Results

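Laser-captured regions of mouse femoral bone marrow were profiled by total RNA sequencing to ask how transcript levels differ between 5 niches recognised under the microscope. These were arteries, sinusoids (the thin-walled venous vessels of the marrow), areas with few sinusoids (low sinusoids), the endosteum (the inner surface of the bone) and the sub-endosteum next to it. The regions were chosen on sections stained for Sca-1, the product of Ly6a, which marks marrow arteries, and for endomucin, the product of Emcn, which marks sinusoids. The comparisons used the 74 regions from 13 slides that the labels mark as passing: 28 arteries, 14 sinusoids, 12 endosteum, 11 low sinusoids and 9 sub-endosteum. The labels tie regions to slides and not to animals, so regions may share an animal, and p-values over regions may then be too small.

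Total counts per region ran from 1056615 to 7634159, with medians of 2654692 in arteries, 4370844.5 in endosteum, 3384052 in low sinusoids, 3364272.5 in sinusoids and 3132076 in sub-endosteum. Protein-coding genes took 24.7% ± 15.9 (SD, n = 74) of the counts and mitochondrial ribosomal RNA 18.2% ± 3.77. Reads assigned to the single annotated gene Gm26917 took 27.9% ± 10.8. The 10 most abundant genes held it beside the ribosomal RNA genes mt-Rnr1, mt-Rnr2 and n-R5-8s1. Whether the reads assigned to Gm26917 come from ribosomal RNA was not tested. The number of protein-coding genes with a count was 7930 ± 3113 (SD, n = 28) in arteries, 8624 ± 3432 (n = 11) in low sinusoids, 10161 ± 2672 (n = 14) in sinusoids, 10394 ± 1930 (n = 9) in sub-endosteum and 11385 ± 2121 (n = 12) in endosteum. Captured areas averaged 12412 ± 4180 µm2 (SD, n = 28) in arteries and 16663 ± 2466 µm2 (n = 12) in endosteum. Of the uniquely placed reads, 54.3% ± 10.5 (SD, n = 74) lay outside exons, with 85.2% in arteries 45 and 83.2% in low sinusoids 29.

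The transcripts of the stained proteins were sparse and are given as a check of the labels, not as a finding. Ly6a had a count in 7 of 28 artery regions, 6 of 12 endosteum, 2 of 11 low sinusoid, 3 of 14 sinusoid and 3 of 9 sub-endosteum regions. It had 53 counts in all arteries together and was too low to be tested. Emcn had a count in 7 of 14 sinusoid regions against 4 of 11 low sinusoid and 4 of 28 artery regions. Its mean level ran against the labels, at 2.41 CPM (98 counts) in low sinusoids and 0.955 (50 counts) in sinusoids, and it was called in no niche by edgeR (adjusted p = 0.329 in low sinusoids, log2 fold change 3.00 ± 1.18). A difference in Emcn was thus not detected.

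Which genes set arteries apart from the mean of the other 4 niches was tested first. Genes of the vessel wall were higher in the artery regions. Rgs5, a regulator of G protein signalling in pericytes and smooth muscle (ENSMUSG00000026678, chromosome 1, 169655501 to 169695813, mm10), stood at 34.4 ± 36.5 CPM (counts scaled to a library of 1e6; SD, n = 28) in arteries and 1.66 ± 4.00 (n = 46) elsewhere. Its log2 fold change was 5.75 ± 0.71 (SE). Ltbp4, which encodes an elastic-fibre protein that binds latent TGF-beta (ENSMUSG00000040488, chromosome 7, 27305136 to 27337692), reached 56.7 ± 97.8 CPM against 4.71 ± 8.41 (log2 3.65 ± 0.54). Myh11, the smooth muscle myosin heavy chain, was 102.9 ± 120.1 CPM in arteries and 7.63 ± 14.9 elsewhere (log2 3.65 ± 0.78). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 9.19e-11 for Rgs5, 4.55e-07 for Ltbp4 and 0.0208 for Myh11. These genes lay above the median of the other regions in 23, 27 and 25 of 28 artery regions. The call of Myh11 was lost without slide 1, 6, 7, 8 or 15 and without arteries 1, 39 or 69 (adjusted p up to 0.337), while Rgs5 and Ltbp4 kept theirs.

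Of 14510 genes tested, 19 passed in arteries, 17 higher and 2 lower, and 1118 had an unadjusted p under 0.05. Other genes that rose were Carmn, a long non-coding RNA of smooth muscle (log2 5.13 ± 0.93, adjusted p = 0.000211), and Fbln2, a fibulin of the vessel matrix (4.00 ± 0.75, 0.000425). Sparcl1, a secreted matricellular protein (4.56 ± 0.85, 0.00041), and Cavin1, a coat protein of caveolae (2.29 ± 0.45, 0.000985), rose as well, all by edgeR. Epas1, a hypoxia-inducible transcription factor abundant in endothelium, Col4a1, a basement membrane collagen, Mcam, Ptprb, an endothelial phosphatase, and Notch3, a receptor of mural cells, rose by log2 1.52 to 3.86 with adjusted p from 0.00766 to 0.0457. Epas1, Col4a1, Mcam, Ptprb and Sparcl1 were not called with captured area as a covariate, nor Mcam with counts summed per slide and niche. Over 13 fits that left out a slide and 28 that left out an artery region, Ptprb kept its call in 5 and 20, Notch3 in 7 and 14, Mcam in 9 and 24, Epas1 in 12 and 27 and Col4a1 in 13 and 28. Tagln, an actin-binding protein of smooth muscle, was 12.6 CPM in arteries against 1.38 in the other regions (adjusted p = 0.00351; not called without slide 6). Against low sinusoids alone it had 1055 counts and 1, a ratio of pooled CPM of 522.2 with a 95% counting interval from 93.5 to 20640. Gja5, a connexin of arterial endothelium, was 6.75 CPM against 1.40 in the other regions (adjusted p = 0.0183), and was not called without slide 14 or 15 or arteries 1, 69 or 74. It had 623 counts in arteries and 3 in sinusoids (ratio for this pair 187.5, 95% interval 63.9 to 911.6). The 2 genes lower in arteries are named after their values were seen. The processed transcript Gm12743 had a count in 5 of 28 artery and 34 of 46 other regions (log2 -5.42 ± 1.18, adjusted p = 0.00766). The pseudogene Gm13542 had a count in 0 of 28 and 15 of 46 (log2 fold of pooled CPM -5.35 or lower with arteries set at 3 counts over the group; fitted log2 fold change -4.39, adjusted p = 0.0321).

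The gene lists described the artery regions in the same terms. All 19 tested members of the arterial endothelium list had a positive log2 fold change, with a median of 2.11 (camera adjusted p = 9.96e-32, and adjusted p = 1.79e-06 with an estimated correlation). In this list 3 members rose, 8 when adjusted over the list alone. Ltbp4 and Fbln2, 2 of those 3, encode matrix proteins that smooth muscle also makes, and Gja5 is endothelial. Of 21 smooth muscle and pericyte genes 19 were positive, with a median of 2.14 (adjusted p = 2.66e-31, and 1.79e-06 with an estimated correlation). Of these 4 rose (Rgs5, Tagln, Myh11 and Notch3), 12 when adjusted over the list alone. Acta2, smooth muscle actin, was 15.3 ± 23.6 CPM (SD, n = 28) with a log2 fold change of 2.29 ± 0.89 that did not pass (adjusted p = 0.429). The niche cytokine and ligand list was higher, with 24 of 34 positive, a median of 0.54 and adjusted p = 1.07e-06 (adjusted p = 0.097 with an estimated correlation). By edgeR 0 of its members passed over all genes and 2 did when adjusted over the list alone. Among its members were the Notch ligands Dll4 (log2 3.42, adjusted p = 0.155) and Jag1 (2.64, 0.173), which the arterial list also holds. Pan-endothelium genes were higher as a list (17 of 23 positive, median 0.46, adjusted p = 1.41e-05; adjusted p = 0.097 with an estimated correlation). Ptprb was the 1 member that rose, over all genes and when adjusted over the list alone. The median was 0.50 with the 1 member at 0 counts in a niche set at its bound.

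Camera also called 5 other lists in arteries. Each lost its call with an estimated correlation, as the niche cytokine and pan-endothelium lists did. CXCL12-abundant reticular (CAR) cell genes (16 of 26 positive, median 0.12, adjusted p = 0.00575) and fibroblast and matrix genes (12 of 22 positive, median 0.05, adjusted p = 0.00611) were higher. Their adjusted p with an estimated correlation was 0.507 and 0.261. In the latter list Col3a1, a fibrillar collagen, had a log2 fold change of 2.76 (adjusted p = 0.0594) and Fmod, fibromodulin, -3.07. Proliferation genes (0 of 28 positive, median -0.59, adjusted p = 2.07e-07), erythroid genes (1 of 29, -0.57, 3.20e-07) and late neutrophil granule genes (1 of 23, -0.76, 1.12e-06) were lower by camera. The adjusted p was 0.22, 0.45 and 0.256 with an estimated correlation. When adjusted over the list alone, 0 CAR cell, 2 fibroblast (1 higher and 1 lower), 0 proliferation, 3 erythroid and 6 late neutrophil genes passed. Hbb-bs, a beta globin, was 68.3 CPM in arteries against 87.5 in low sinusoids and 146.3 to 226.6 in endosteum, sinusoids and sub-endosteum (log2 -0.92, adjusted p = 0.218). S100a9 had a log2 fold change of -1.12 (adjusted p = 0.0844). The median log2 fold change of all tested genes in this comparison was -0.26, and arteries had the fewest coding genes with a count.

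The number of genes called in arteries was 208 with DESeq2 (62 higher, 146 lower), 1073 with limma-voom (67 higher, 1006 lower) and 268 without the slide term (234 higher, 34 lower). Of these 16, 16 and 17 were among the 19. Leaving out arteries 39 or arteries 69 gave 12 genes, leaving out arteries 8 gave 30, and leaving out slide 1 gave 32. The p-values may also be too small because regions may share an animal.

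At the endosteum, genes of bone-forming cells were higher than in the mean of the other niches. Col1a1 and Col1a2 encode the chains of type I collagen. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) reached 4114 ± 5163 CPM (SD, n = 12) against 84.4 ± 291.1 (n = 62) elsewhere, a log2 fold change of 6.17 ± 0.73. Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544) reached 2031 ± 2432 against 99.2 ± 191.7 (log2 4.48 ± 0.43). Sparc, or osteonectin, a collagen-binding matrix protein, was 266.5 ± 304.1 CPM against 31.0 ± 27.2 (log2 3.14 ± 0.42). The adjusted p by edgeR was 4.75e-08 for Col1a1, 1.10e-10 for Col1a2 and 3.19e-08 for Sparc. In the same order 12, 12 and 10 of 12 endosteum regions lay above the median of the others.

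In this comparison 29 of 14510 genes passed, each of them higher. An unadjusted p under 0.05 was found for 614, less than a share of 0.05 of the genes tested. In simulated counts edgeR found 88% of rises of log2 4 in endosteum and 24% of falls of that size, so lower genes were more often missed. Dcn, the proteoglycan decorin (log2 5.81 ± 1.097, adjusted p = 0.000424), Col11a1 (5.65 ± 0.94, 0.00045) and Serpinh1, a chaperone of collagen folding (3.22 ± 0.70, 0.00676), rose with them by edgeR. So did Col22a1 (3.48 ± 0.76, 0.00787), Col11a2 (3.30 ± 0.66, 0.00823) and Col5a2 (3.74 ± 0.79, 0.0133). Dcn and Col22a1 were not called by DESeq2, nor were Metrnl and Zfp472 below, and Dcn, Col22a1, Col11a2 and Col5a2 were not with the number of coding genes with a count as a covariate. Col11a1, Col22a1 and Col5a2 were not called with counts summed per slide and niche, and Serpinh1 and Col22a1 were not without the slide term. Calls were also lost without slide 6 (Serpinh1), slide 7 (Col22a1), slide 5 (Col5a2), endosteum 3 (Col22a1, Col11a2 and Col5a2), endosteum 41 (Col22a1) and endosteum 23 (Col5a2). A further 3 genes had 1 to 3 counts in low sinusoids. Cpe, a carboxypeptidase, was 11.6 CPM in endosteum against 1.92 in the other regions (adjusted p = 0.000122). It had 970 counts in endosteum and 1 in low sinusoids (ratio of pooled CPM for this pair 569, 95% counting interval 101.9 to 22500). Metrnl, a secreted protein, was 3.42 CPM against 1.09 in the other regions (adjusted p = 0.0113), with 308 counts and 3 in that pair (ratio 60.2, 20.4 to 293.6). Nhej1, a DNA end-joining factor, was 4.07 CPM against 1.30 (adjusted p = 0.0132), with 253 counts and 3 in that pair (ratio 49.5, 16.7 to 241.5). Zfp472, a zinc finger gene, had no count in low sinusoids, so that its log2 fold of pooled CPM was at least 1.94 with that niche set at 3 counts over the group (adjusted p = 0.00564). Metrnl, Nhej1 and Zfp472 were not called without the slide term, with summed counts, with the number of coding genes as a covariate or without endosteum 37, and each also lost its call without 2 of the slides (1 and 6, 5 and 10, and 6 and 10). Bglap, osteocalcin, was too sparse to be tested, with a count in 9 of 12 endosteum regions (1022 counts) and in 1 of 28 artery, 1 of 14 sinusoid, 1 of 9 sub-endosteum and 0 of 11 low sinusoid regions.

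All 24 tested osteoblast genes had a positive log2 fold change at the endosteum, with a median of 2.93 (camera adjusted p = 2.95e-32, and 4.30e-06 with an estimated correlation). Of them 6 rose, 15 when adjusted over the list alone. The osteocyte list was higher in all 6 tested members (median 2.74, adjusted p = 0.000226; adjusted p = 0.0569 with an estimated correlation). Dmp1, a matrix phosphoprotein of osteocytes (log2 4.88 ± 1.13, adjusted p = 0.0156), and Sost, the Wnt inhibitor sclerostin (4.37 ± 1.095, 0.0376), were the 2 that rose, 4 when adjusted over the list alone. Sost kept its call in 7 of 12 fits without a slide, 6 of 12 without a region and 7 of 14 other settings, and was lost with DESeq2, limma-voom, no slide term and summed counts. Dmp1 kept its call in 10 of 13, 10 of 12 and 11 of 15, and was lost with DESeq2 and summed counts. The chondrocyte list split evenly, with 6 of 12 members positive and a median of -0.03. Camera did not call it (adjusted p = 0.093, and 0.507 with an estimated correlation), while fry called it higher (adjusted p = 0.0163), and Col11a1 and Col2a1 were the 2 members that rose. Fry also called interferon response genes higher (11 of 17 positive, median 0.27, adjusted p = 0.0216), with 0 members called by edgeR and camera adjusted p of 0.0934, and 0.587 with an estimated correlation.

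Granulocyte genes were also higher at the endosteum. All 23 late neutrophil granule genes were positive, with a median of 1.17 (adjusted p = 3.56e-15, and 0.0398 with an estimated correlation). The median was 0.72 with the number of coding genes with a count as a covariate, and the list was still called. Among its members 4 rose, 9 when adjusted over the list alone. S100a9, a calcium-binding protein of neutrophils, was 253.3 ± 133 CPM (SD, n = 12) against 112 ± 93.9 (n = 62; log2 1.53 ± 0.32, adjusted p = 0.00474 by edgeR). Its partner S100a8 was 108.9 ± 62.1 CPM (log2 1.70 ± 0.41, 0.0229). Camp, a granule antimicrobial peptide, was 205 ± 123.4 CPM against 87.6 ± 66.4 (log2 1.42 ± 0.32, 0.0113), and Ngp, another granule protein, had log2 1.05 ± 0.25 (0.0236). Early neutrophil granule genes were positive in 15 of 16 (median 1.00, adjusted p = 1.14e-06; adjusted p = 0.133 with an estimated correlation). Elane, neutrophil elastase (log2 2.25 ± 0.53, adjusted p = 0.0157), and Mpo, myeloperoxidase (1.41 ± 0.33, 0.0186), were the 2 that rose, 3 when adjusted over the list alone. The calls of all 6 of these genes were lost without the slide term, with the number of coding genes with a count as a covariate, and without endosteum 23 or endosteum 37. Of 13 fits that left out a slide, S100a9 kept its call in 11, S100a8 in 9, Camp in 12, Ngp in 8, Elane in 8 and Mpo in 10, and DESeq2 did not call S100a8, Ngp or Mpo. Ngp and Mpo were not called with counts summed per slide and niche either.

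Megakaryocyte and platelet genes (24 of 24 positive, median 1.21, adjusted p = 3.06e-05), monocyte and macrophage genes (24 of 27, 0.67, 0.0261) and plasma cell genes (12 of 13, 0.86, 0.0465) were called higher at the endosteum by camera. Under an estimated correlation the adjusted p was 0.585, 0.637 and 0.507. Treml1, a platelet granule receptor, had a log2 fold change of 2.14 (adjusted p = 0.775) and Igkc, an immunoglobulin light chain, 1.86 (0.602). Endosteum regions had the most coding genes with a count, and the median log2 fold change of all genes was 0.21. The count of 29 genes was 13 without the slide term, 12 with counts summed per slide and niche and 7 with the number of coding genes with a count as a covariate. It was 16 without slide 1, 18 without endosteum 23 and 19 without endosteum 37. Regions of 1 animal may be among the 12, which would make these p-values too small.

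Sinusoids were compared with the mean of the other niches in the same fit. The sinusoidal endothelium list was higher, with 19 of 21 genes positive, a median of 0.83 and adjusted p = 2.50e-07 by camera (adjusted p = 0.0698 with an estimated correlation). Its leading gene was Stab2, a hyaluronan scavenger receptor of sinusoidal endothelium, at 132.9 ± 60.4 CPM (SD, n = 14) in sinusoids, 28.4 ± 26.1 (n = 11) in low sinusoids and 49.2 to 72.9 in the other 3 niches. Its log2 fold change of 1.34 ± 0.36 did not pass over all genes (adjusted p = 0.263 by edgeR) and was the 1 member to pass when adjusted over the list alone. CAR cell genes (20 of 26 positive, median 0.51, adjusted p = 0.00471) and megakaryocyte and platelet genes (16 of 24, 0.24, 0.0365) were higher by camera and arterial endothelium genes lower (11 of 19 negative, median -0.74, adjusted p = 0.00383). Their adjusted p was 0.507, 0.867 and 0.392 with an estimated correlation. Adipoq, adiponectin, which CAR cells express, was 25.9 ± 17.8 CPM in sinusoids (log2 2.10 ± 0.71, adjusted p = 0.546).

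A single gene passed in sinusoids, Ltbp4, which fell (log2 -4.03 ± 0.77, adjusted p = 0.00385) to 0.858 ± 1.31 CPM (SD, n = 14) against 29.9 ± 71.2 (n = 60), below the median of the others in 14 of 14 regions. At an unadjusted p under 0.05 there were 597 genes, less than a share of 0.05 of those tested. DESeq2 called 62 (50 higher, 12 lower) and limma-voom 6 (3 higher, 3 lower). The call of Ltbp4 was lost with counts summed per slide and niche and without slide 13 or slide 14. Leaving out slide 3, 4, 5, 6, 7, 8 or 10 gave 5, 3, 2, 10, 3, 2 and 4 genes, and leaving out sinusoids 43 or 46 gave 2. That regions may share an animal holds here too, so that the p-values may be too small.

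In the areas with few sinusoids, 16 genes and 10 gene lists were lower than in the mean of the other niches. The lists were mainly of stromal, vascular and megakaryocytic cells, and 1 of them, CAR cell genes, was also called with an estimated correlation. Cavin1 (ENSMUSG00000004044, chromosome 11, 100956733 to 100970887) had a count in 3 of 11 low sinusoid regions and 61 of 63 others, at 0.735 ± 1.62 CPM (SD, n = 11) against 35.2 ± 35.4 (n = 63). It fell by log2 5.28 ± 0.81 (adjusted p = 1.68e-06 by edgeR). Sparc was 10.5 ± 11.9 CPM against 79.4 ± 159.3 (log2 -2.99 ± 0.61, adjusted p = 0.00558). Actb, cytoskeletal actin, was 217.5 ± 149 against 430 ± 306 (log2 -1.23 ± 0.30, 0.0242). Cd226, an adhesion receptor of platelets and lymphocytes, had a count in 0 of 11 regions and 34 of 63 others, a log2 fold of pooled CPM of -7.08 or lower with low sinusoids set at 3 counts over the group (adjusted p = 0.00558). Pros1, the anticoagulant protein S, had 3 counts in low sinusoids and 2940 elsewhere (ratio of pooled CPM 0.00692, 95% counting interval 0.00143 to 0.0203; adjusted p = 0.0175). Gucy1b1, a subunit of soluble guanylate cyclase, had 1 and 2137 (ratio 0.00317, 8.03e-05 to 0.0177, adjusted p = 0.0242). Cavin1 and Cd226 kept their calls under all settings run, while without the 2 libraries with over 80% of unique reads outside exons, and without slide 6, Sparc, Actb, Pros1 and Gucy1b1 were not called. Actb, Pros1 and Gucy1b1 were also lost without slide 1 and without low sinusoids 29 or 6.

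Of the 14510 genes 73 passed in low sinusoids, 57 higher and 16 lower, and 1239 had an unadjusted p under 0.05. The higher genes were sparse: 11 of the 57 had a count in at least 50% of the low sinusoid regions. The first of these was Fuom, a fucose mutarotase, with a count in 6 of 11 regions and 19 of 63 others (log2 5.60 ± 1.23, adjusted p = 0.00965 by edgeR). Cdh22, a cadherin, followed (log2 4.44 ± 1.07, 0.0242). Neither was called by limma-voom, with summed counts, or without slide 6, low sinusoids 29 or low sinusoids 6. The other 9, Mlxipl, Abcc6, Ppfia3, Lrfn1, Egr2, Islr2, Cd276, Chrm1 and Aloxe3, had log2 fold changes from 4.03 to 5.16 with adjusted p from 0.0255 to 0.0488. Mean CPM differed less than these fitted values in Cdh22 (8.32 in low sinusoids against 5.54 elsewhere), Abcc6 (8.25 against 4.49), Ppfia3 (10.8 against 4.35), Lrfn1 (5.27 against 2.49) and Islr2 (3.52 against 1.56). The same held for Aloxe3 (9.76 against 2.85), Cd276 (6.79 against 1.72) and Egr2 (6.86 against 1.29). It held as well for Mlxipl (9.51 against 1.81), Chrm1 (11.6 against 2.07) and Fuom (12.9 against 1.07). Under other settings or leave-outs the log2 fold change fell to 2.08 for Fuom, to 2.21 for Cdh22 and to between 1.57 and 2.30 for each of the 9. Without low sinusoids 29, the library with 83.2% of unique reads outside exons, 2 of the 57 were still called, and without low sinusoids 6 there were 5. Of the 57 genes, 56 had a count in low sinusoids 29, 52 in low sinusoids 6 and 54 in arteries 45, against a median of 15 over the low sinusoid regions. The median was 13.5 in endosteum, 11 in sinusoids, 9 in sub-endosteum and 7 in arteries. Among other single regions, sinusoids 60 had a count for 43, endosteum 49 for 42, and arteries 25 and arteries 48 for 40 each.

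**Figure D1:**
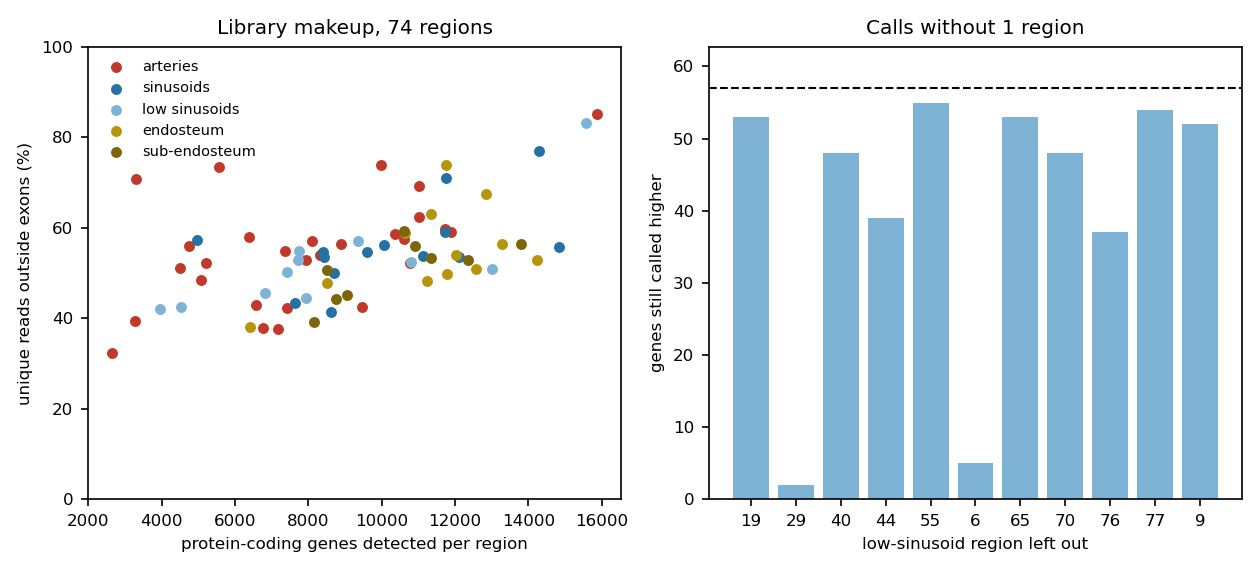
Left, percent of unique reads outside exons (y axis) against protein-coding genes with a count (x axis) for each of the 74 regions, coloured by niche; arteries 45 (85.2%) and low sinusoids 29 (83.2%) stand at the upper right. Right, number of the 57 genes called higher in low sinusoids (dashed line) that were still called when the low sinusoid region on the x axis was left out, 2 without low sinusoids 29 and 5 without low sinusoids 6.

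Among the lists, CAR cell genes were lower in low sinusoids in 24 of 26 members (median -1.21, camera adjusted p = 1.79e-10, and 0.0398 with an estimated correlation). Igfbp5, an IGF-binding protein (log2 -1.37 ± 0.36, adjusted p = 0.0398), and Adipoq (-3.72 ± 0.99, 0.0465) fell, and 4 members did when adjusted over the list alone. Of the 11 fits that left out a low sinusoid region, Adipoq kept its call in 1 and Igfbp5 in 5; of the 13 that left out a slide, in 6 and 8; and of 15 other settings, in 9 and 7. Cxcl12, the chemokine that retains stem and progenitor cells in the marrow, was 77.6 ± 69.03 CPM (SD, n = 11) in low sinusoids and 132.5 to 181 in the other niches (log2 -1.21 ± 0.40, adjusted p = 0.147). Megakaryocyte and platelet genes were negative in 23 of 24 (median -1.89, adjusted p = 4.40e-11; adjusted p = 0.248 with an estimated correlation). Treml1 fell (log2 -4.94 ± 1.24, adjusted p = 0.0393), and 3 genes did when adjusted over the list alone. Its call was kept in 5 of the 11 fits without a region, 7 of the 13 without a slide and 11 of 15 other settings. It was lost without the slide term, with summed counts, without the 2 libraries with over 80% of unique reads outside exons and with that share as a covariate. Pf4, platelet factor, was 15.1 ± 15.2 CPM against 74.5 to 136.7 in the other niches (log2 -2.91 ± 0.96, adjusted p = 0.182). Sinusoidal endothelium genes were negative in 17 of 21 (median -1.09, adjusted p = 8.94e-07; adjusted p = 0.0815 with an estimated correlation). Stab2 stood at log2 -1.17 ± 0.45 (adjusted p = 0.289).

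Camera called 7 more lists lower in low sinusoids. These were pan-endothelium (19 of 23 negative, median -0.88, adjusted p = 0.000199), smooth muscle and pericyte (19 of 21, -1.41, 0.000221) and late neutrophil granule genes (19 of 23, -0.69, 0.00719). The others were osteoblast (15 of 24, -0.65, 0.0109), niche cytokine and ligand (25 of 34, -0.98, 0.0116), monocyte and macrophage (23 of 27, -0.61, 0.0161) and fibroblast and matrix genes (16 of 22, -0.85, 0.0264). With an estimated correlation their adjusted p was 0.159, 0.21, 0.641, 0.528, 0.507, 0.587 and 0.45. The fibroblast median was -0.70 with members at 0 counts in a niche set at their bounds. Adjusted over the list alone, 2 pan-endothelium, 2 smooth muscle, 2 late neutrophil, 2 niche cytokine (1 higher and 1 lower) and 5 osteoblast genes passed, against 1 osteoblast gene, Sparc, over all genes. T and NK cell genes (8 of 14 positive, median 0.31, adjusted p = 0.0116) and skeletal muscle genes (11 of 13, 1.35, 0.0179) were called higher, with adjusted p of 0.248 and 0.507 with an estimated correlation. The leading members were Cd247, a T cell receptor chain (log2 2.47, adjusted p = 0.597), and Tnnt3, a muscle troponin (3.11, 0.332).

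The count of 73 genes in low sinusoids was 46 (33 higher, 13 lower) with DESeq2 size factors and 48 (31 higher, 17 lower) with TMMwsp factors, which moved the median of all genes by -0.13 on the log2 scale. With no filter on low counts it was 855 (794 higher, 61 lower), with counts summed per slide and niche 9 (0 higher), without the 2 libraries with over 80% of unique reads outside exons 4 (0 higher), and with that share as a covariate 27 (17 higher). It was 264 (88 higher, 176 lower) with DESeq2, 168 (4 higher, 164 lower) with limma-voom. There were 7 genes without low sinusoids 29, 8 without low sinusoids 6 and 124 without low sinusoids 55. Leaving out slide 1, 4, 6, 8, 10 or 14 gave 36, 124, 2, 20, 177 and 32 genes. Shared animals among regions may make the p-values too small.

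**Figure D2:**
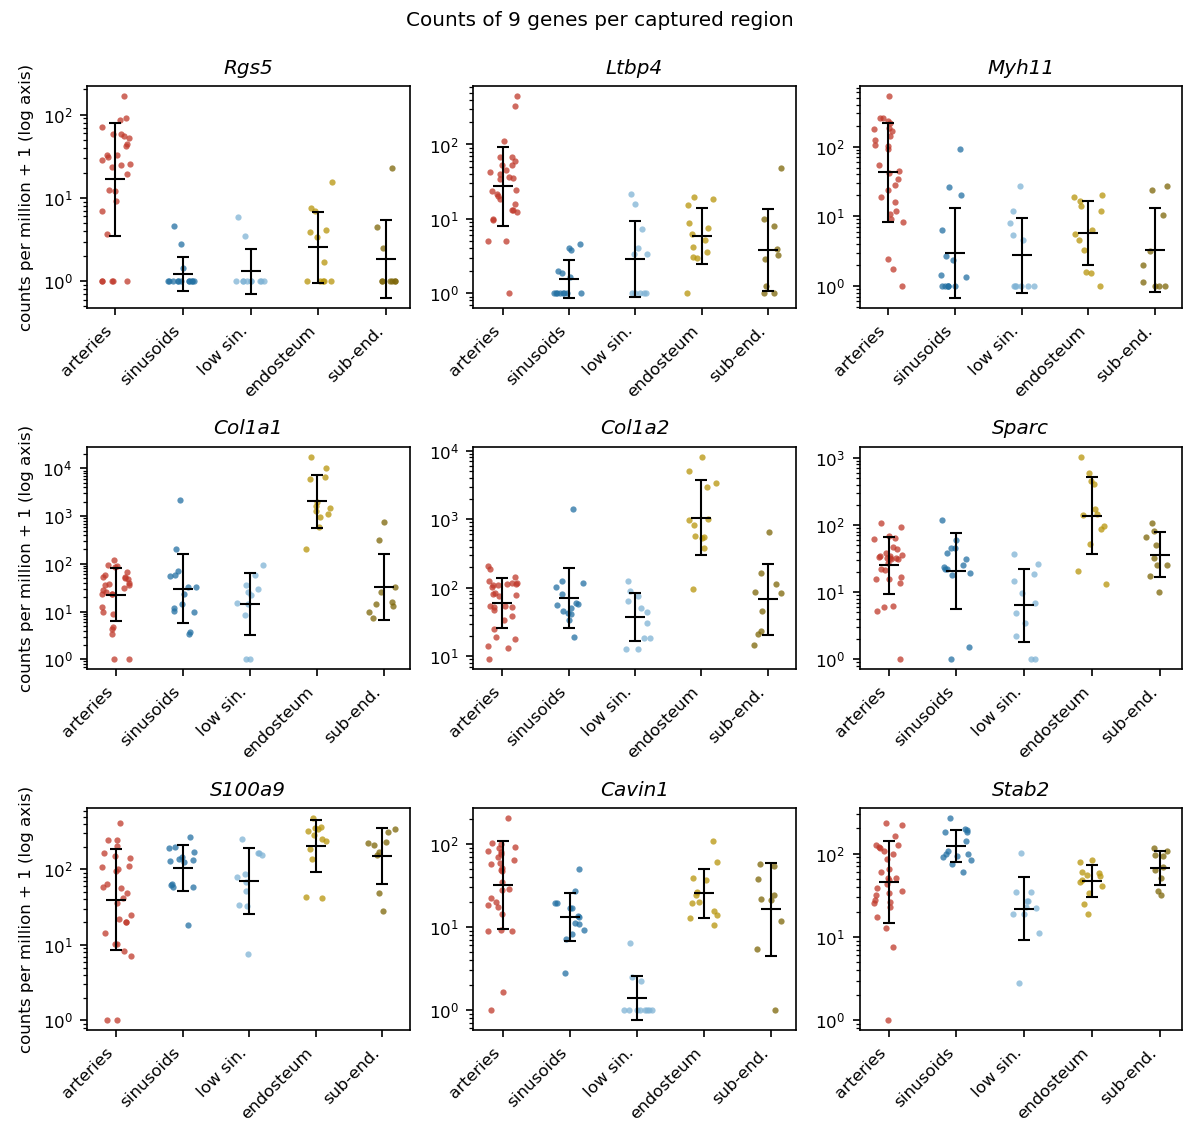
CPM plus 1 (log axis) of 9 genes in each of the 74 regions, with one point per region and, on the log scale, the mean (long bar) and SD (whiskers) of each niche. Rgs5, Ltbp4 and Myh11 stand highest in arteries, Col1a1, Col1a2 and Sparc in the endosteum, Stab2 in sinusoids, and Cavin1 lowest in low sinusoids.

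No single gene was found to differ between the sub-endosteum and the mean of the other niches by edgeR: 0 of 14510 passed, and the smallest adjusted p was 0.544. An unadjusted p under 0.05 was found for 627, less than a share of 0.05 of the genes tested. In simulated counts edgeR found 58% of rises and 22% of falls of log2 4 in this niche, and 10% and 2% of those of log2 2. Differences of that size could thus be missed. DESeq2 called 116 (15 higher, 101 lower) and limma-voom 5 (2 higher, 3 lower), and 1 gene passed when slide 1 was left out. Camera called 4 lists higher. Megakaryocyte and platelet genes were positive in 22 of 24 (median 0.66, adjusted p = 4.18e-06) and erythroid genes in 29 of 29 (0.36, 0.000381). Positive too were interferon response genes in 13 of 17 (0.62, 0.0153) and CAR cell genes in 20 of 26 (0.38, 0.0182). With an estimated correlation the 4 adjusted p were 0.507, 0.641, 0.41 and 0.587. Hbb-bs averaged 226.6 ± 169.9 CPM (SD, n = 9; log2 0.64 ± 0.37) and Pf4 136.7 ± 83.3, and among interferon genes Mx2 had a log2 fold change of 2.41 and Ifit1 of -2.54.

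Camera called 4 lists lower in the sub-endosteum: arterial endothelium (15 of 19 negative, median -1.52, adjusted p = 2.84e-05), osteoblast (18 of 24, -0.83, 0.00239), chondrocyte (11 of 12, -1.08, 0.00433) and smooth muscle and pericyte genes (15 of 21, -0.54, 0.0286). With an estimated correlation their adjusted p was 0.133, 0.45, 0.182 and 0.585. Of the genes of these lists 1, the cartilage collagen Col9a2, passed when adjusted over the list alone. Col9a2 had 3 counts in the sub-endosteum and 668 elsewhere (ratio of pooled CPM 0.0239, 95% counting interval 0.00491 to 0.07). Fbln2 had a log2 fold change of -2.74 and Smpd3, a sphingomyelinase of bone and cartilage, of -3.87 (adjusted p = 0.544), while Tpm2, a tropomyosin, was at 2.02. The sub-endosteum held 9 regions, some of which may come from 1 animal, in which case the p-values are too small.

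**Figure D3:**
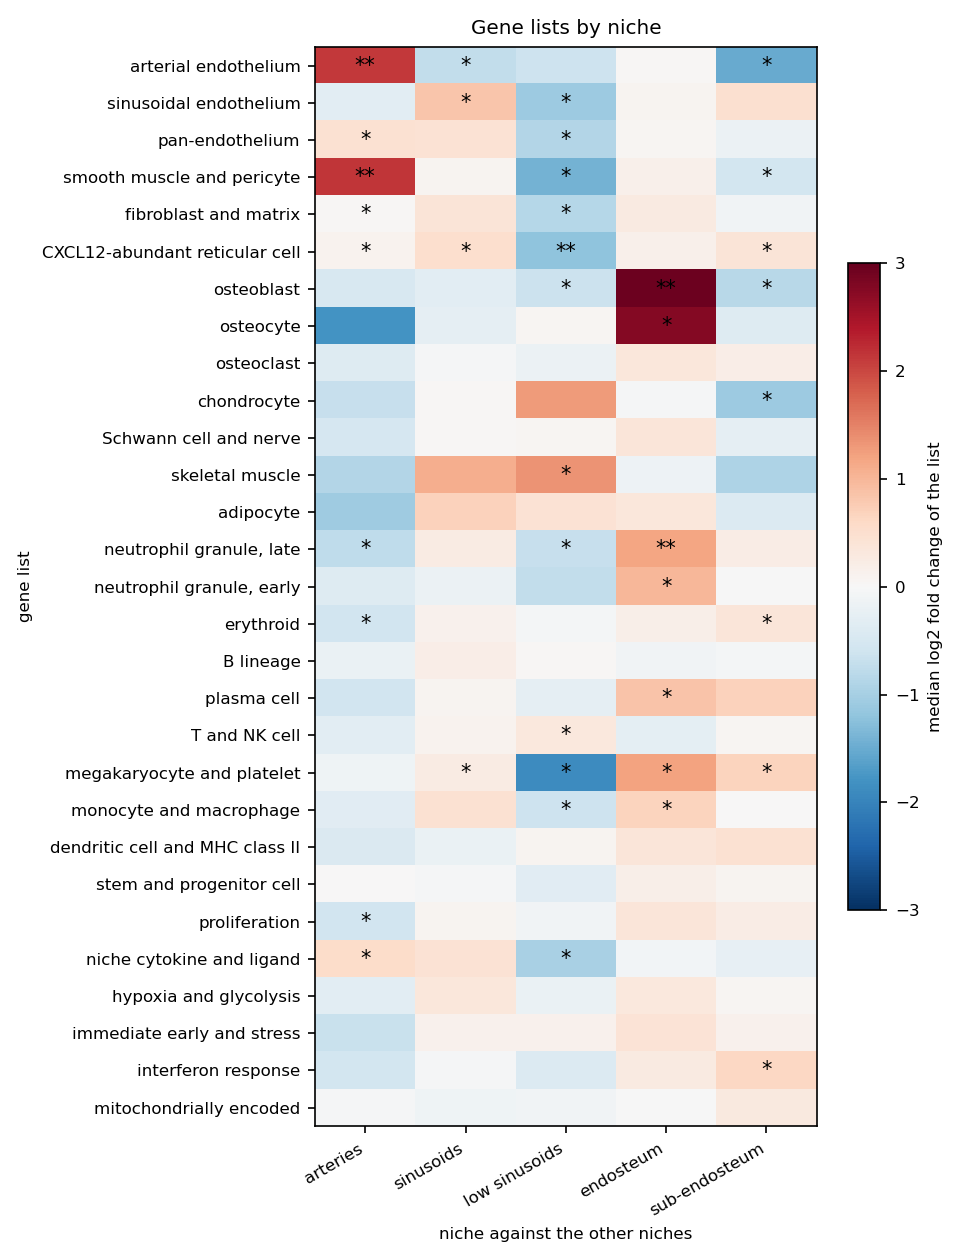
Median log2 fold change (colour scale from -3 to 3) of each of the 29 fixed gene lists (y axis) in each niche against the mean of the other niches (x axis). A single star marks a list called by camera with the preset correlation and a double star one also called with an estimated correlation, as the osteoblast list (median 2.93) in the endosteum.

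Arteries and sinusoids, the stained vessel types, were compared directly. Ltbp4 (56.7 ± 97.8 CPM, SD, n = 28, against 0.858 ± 1.31, n = 14; log2 6.15 ± 0.88, adjusted p = 1.96e-07) and Rgs5 (log2 7.31 ± 1.16, adjusted p = 4.67e-06) were higher in arteries by edgeR. Lower in arteries were Rasgrf1, a guanine nucleotide exchange factor, with a count in 5 of 28 artery and 10 of 14 sinusoid regions (log2 -6.37 ± 1.41, 0.0257), and Slc12a8, a solute carrier, in 5 of 28 and 8 of 14 (-6.27 ± 1.42, 0.0331). Ern2, an endoplasmic reticulum stress sensor named after its values were seen, was lower too, with a count in 5 of 28 and 6 of 14 (-7.13 ± 1.52, 0.0142). Mean CPM differed less, at 1.38 in arteries against 3.45 in sinusoids for Rasgrf1 and 3.06 against 6.01 for Slc12a8. Without the slide term their log2 fold changes were -1.29 and -0.96, and neither was called then, nor with limma-voom, summed counts or area as a covariate. Rasgrf1 kept its call in 8 of 13 fits that left out a slide and Slc12a8 in 7. These 5 of 14510 genes passed and 933 had an unadjusted p under 0.05. Arterial endothelium (16 of 19 positive, median 2.47, camera adjusted p = 9.76e-21) and smooth muscle genes (17 of 21, 1.45, 1.06e-16) were higher in arteries, and also with an estimated correlation (adjusted p = 9.12e-05 and 0.000488). Sinusoidal endothelium genes were higher in sinusoids, with 2 of 21 positive (median -0.95, adjusted p = 0.00434; adjusted p = 0.538 with an estimated correlation). DESeq2 called 102 genes and limma-voom 252, and leaving out slide 4, 6, 7, 8, 10, 13 or 15 gave 16, 3, 3, 10, 9, 9 and 3. The p-values may be too small where regions share an animal.

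Sinusoids were then set against low sinusoids. Cavin1 was higher in sinusoids, at 15.1 ± 11.4 CPM (SD, n = 14) with a count in 14 of 14 regions against 3 of 11 (log2 4.25 ± 0.81, adjusted p = 0.00252 by edgeR). The other 2 of the 3 genes called are named after their values were seen. The small nuclear RNA Gm26317 had a count in 6 of 14 sinusoid and 0 of 11 low sinusoid regions (a log2 fold of pooled CPM of at least 9.02 with low sinusoids at 3 counts over the group, adjusted p = 0.0262). Matn1, a cartilage matrix protein, had 3 counts in sinusoids and 238 in low sinusoids (ratio 0.00691, 95% counting interval 0.00142 to 0.0204, adjusted p = 0.0262). Sinusoidal endothelium (19 of 21 positive, median 1.21, adjusted p = 3.68e-10) and CAR cell genes (24 of 26, 1.30, 5.42e-10) were higher in sinusoids, and also with an estimated correlation (adjusted p = 0.0119 and 0.0341). Megakaryocyte and platelet genes (23 of 24, 1.61, 8.09e-11) and pan-endothelium genes (18 of 23, 0.91, 0.000423) were higher by camera, with adjusted p of 0.3 and 0.169 with an estimated correlation. An unadjusted p under 0.05 was found for 811 genes, DESeq2 called 63 and limma-voom 41. Leaving out slide 1, 5, 6, 8, 10, 13, 14 or 15 gave 0, 1, 1, 1, 22, 1, 5 and 1 genes. Regions of one animal may make the p-values too small.

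Between endosteum and sub-endosteum 1 gene passed, Col1a2, at 2031 ± 2432 CPM (SD, n = 12) against 133.5 ± 202.8 (n = 9; log2 4.45 ± 0.73, adjusted p = 0.00141 by edgeR). It was higher than the sub-endosteum median in 12 of 12 endosteum regions. Osteoblast genes were higher in 23 of 24 members (median 2.73, camera adjusted p = 1.44e-20, and 0.000314 with an estimated correlation). Osteocyte (6 of 6 positive, median 2.34, adjusted p = 0.00108), chondrocyte (9 of 12, 1.40, 0.000752) and late neutrophil granule genes (18 of 23, 0.77, 0.00152) were higher by camera. The adjusted p with an estimated correlation was 0.078, 0.0779 and 0.696. At an unadjusted p under 0.05 there were 481 genes, less than a share of 0.05 of those tested. DESeq2 called 97 and limma-voom 8. Col1a2 was not called with counts summed per slide and niche (adjusted p = 0.171). Leaving out slide 6, 8 or 14 gave 2, 2 and 3 genes. Here as well regions may share an animal, and the p-values may be too small.

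Whether transcript levels followed the distance from the endosteum was tested among the 28 artery regions, whose distances ran from 35 to 550 in a unit the labels do not state. Of 1581 genes with enough counts, edgeR called 0, with a smallest adjusted p of 0.972, and DESeq2 called 1. An unadjusted p under 0.05 by edgeR was found for 18, less than a share of 0.05 of the genes tested. In counts simulated for this comparison a slope of 1 on the log2 scale per 100 distance units was found for 73 of 100 genes and a slope of 0.5 for 8 of 100, so slopes of that size were mostly missed with these counts and this spread. Regions sharing an animal may make the p-values too small. Over all 5 niches together, the 4 degree of freedom test called 95 genes (1194 at an unadjusted p under 0.05), led by Rgs5 (adjusted p = 4.53e-10), Col1a2 (2.74e-09), Ltbp4 (6.17e-08), Sparc (4.87e-07) and Cavin1 (6.39e-07). Without slide 6 it called 34, and the same limit from shared animals holds.

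Several genes fixed beforehand for their role in marrow niches passed in no niche. Kitl, stem cell factor, was 8.54 ± 12.2 CPM in arteries (SD, n = 28), 6.18 ± 6.14 in endosteum, 1.64 ± 2.22 in low sinusoids, 5.43 ± 6.20 in sinusoids and 10.8 ± 8.07 in sub-endosteum. Lepr, the leptin receptor of marrow stroma, lay between 18.2 and 33.95 CPM in all 5 niches. Il7, a lymphoid cytokine, had a count in 8 of 28 artery, 2 of 12 endosteum, 1 of 11 low sinusoid, 3 of 14 sinusoid and 3 of 9 sub-endosteum regions. The endothelial genes Cdh5 and Pecam1 were 11.02 ± 16.1 and 24.4 ± 28.2 CPM in arteries and 9.02 ± 10.2 and 21.2 ± 19.9 in sinusoids. Sox17, an arterial transcription factor, had a count in 15 of 28 artery and 9 of 14 sinusoid regions. The osteoclast genes Acp5 and Ctsk averaged 19.7 and 9.31 CPM in the endosteum and 10.9 to 23.8 and 0.936 to 9.03 in the other niches, with Acp5 highest in low sinusoids. The matrix gene Spp1 averaged 4.25 CPM in the endosteum, 9.33 in sinusoids and 0.28 in low sinusoids (log2 -4.88 ± 1.77, adjusted p = 0.244). Over the 5 niches the macrophage gene C1qa ranged from 5.31 to 15.1 CPM, the B cell gene Cd79a from 2.69 to 6.21 and the stem and mast cell receptor Kit from 8.56 to 13.9. Mki67, a proliferation marker, ranged from 350.6 ± 171.8 CPM in arteries to 557 ± 143.6 in sub-endosteum. Mpz, a myelin gene, had a count in 7 of 28 artery, 3 of 12 endosteum, 3 of 11 low sinusoid, 2 of 14 sinusoid and 1 of 9 sub-endosteum regions. Its log2 fold change in low sinusoids was 2.81 ± 1.26 (adjusted p = 0.459 by edgeR).

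The lists that camera called in no niche were the mitochondrially encoded genes, with a smallest adjusted p of 0.106 over the 5 niches, adipocyte genes (0.177, though called lower in arteries by fry at 0.0393), Schwann cell and nerve genes (0.202), dendritic cell and MHC class II genes (0.214), stem and progenitor genes (0.241), B lineage genes (0.368), osteoclast genes (0.394), hypoxia and glycolysis genes (0.394) and immediate early and stress genes (0.591).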

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

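Which regions stood apart was tested by a rule fixed before the data were examined; the genes it was applied to follow from the naming rule. Only the sub-endosteum, with 9 regions, had a size the rule covers. Of 61 values tested there 24 had a region far from the nearest other, where chance gives 1 in 20, or 3.05; many of the genes are sparse, so that a single region with counts stands apart from zeros.

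Sub-endosteum 14 had a total count of 7634159 against a niche median of 3132076, and 4919693 protein-coding counts against a median of 671363. It also held the only Col9a2 signal of the niche (0.128 CPM) and the highest Ifit1 (5.37 CPM, median 0.52). Sub-endosteum 18 was highest for Ly6a (4.39 CPM), Acta2 (22.6 CPM, median 0.385), Bglap (6.90 CPM, the only signal) and Car3 (1.26 CPM), and had 0 CPM of Lepr against a median of 20.8. Sub-endosteum 57 was highest for Sox17 (1.04 CPM) and lowest for Pf4 (11.6 CPM, median 132.7) and Tpm2 (0 CPM, median 32.6). Sub-endosteum 24 was highest for Acan (5.77 CPM) and Mpz (4.62 CPM, the only signal) and lowest for Serping1 (2.31 CPM, median 15.6) and Tal1 (10.4 CPM, median 73.7). Sub-endosteum 38 had 0 CPM of Adipoq (median 13.8) and of Kit (median 10.2) and the highest Des (3.47 CPM). Sub-endosteum 72 was highest for Il7 (7.67 CPM) and Sp7 (2.56 CPM) and held the only Cpz (0.639 CPM), and sub-endosteum 11 the only Gja4 (1.32 CPM) and Gja5 (1.77 CPM).

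In regions that entered no comparison, counts above the limit that a count of 0 allows were seen for niche genes. Bglap had 14 counts in sub-endosteum 31 and 11 in sub-endosteum 50, both marked as outliers in a principal component analysis, and Stab2 had 15 counts in high sinusoids 51 and 17 in high sinusoids 62, both marked for insufficient reads. High sinusoids 62 also had 48 counts of Myh11, a smooth muscle gene that was higher in arteries. Other counts there were 112 of Stab2 and 113 of Pf4 in sub-endosteum 31, and 128 of Pecam1 and 132 of Stab2 in sub-endosteum 50. Arteries 61, with 181810 counts and 166 coding genes with a count, had none of the 26 genes fixed beforehand.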

How the results depend on the processing

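Settings chosen after the data were seen are the covariates for reads outside exons and for detected coding genes, and the removal of 2 libraries or of the region absent from the authors' table. None of the 301 named gene results reversed while past the threshold under the settings run. Of 62 called ones, 56 stayed called with DESeq2 size factors, 56 with TMMwsp factors, 56 without the filter, 47 with limma-voom, 34 without the slide term and 33 with summed counts. With DESeq2 it was 45 of the 60 that could be compared. Depth and the spread between regions together limit the calls. With the observed ones, simulated rises of log2 2 were found for 10% to 50% of genes, depending on the niche, and falls of log2 2 for 2% to 16%. The simulation varied neither, so it does not separate them. The cause of the changes below was not tested.

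With no filter the genes called were 62 in arteries (34 higher, 28 lower; 19 with the filter), 47 in endosteum (29), 855 in low sinusoids (794 higher, 61 lower; 73), 74 in sinusoids (1) and 11 in sub-endosteum (0). They were 34 for arteries against sinusoids (5), 20 for sinusoids against low sinusoids (3), 13 for endosteum against sub-endosteum (1), 934 over all niches (95) and 1 for distance (0). On the authors' genes they were 34 in arteries, 45 in endosteum, 803 in low sinusoids, 42 in sinusoids, 15 for arteries against sinusoids and 927 over all niches. That setting drops the filter on low counts as well, so it differs from the main fit in both respects. DESeq2 called 208 in arteries (62 higher, 146 lower), 264 in low sinusoids (88 and 176), 62 in sinusoids and 116 in sub-endosteum. It called 102, 63 and 97 for the pairs in that order, 33 over all niches and 1 for distance. Limma-voom called 1073 in arteries (67 higher, 1006 lower), 56 in endosteum, 168 in low sinusoids (4 and 164), 6 in sinusoids, 5 in sub-endosteum, 252, 41 and 8 for the pairs and 1243 over all niches; it was not run for distance. Without the slide term there were 268 in arteries, 13 in endosteum, 40 in low sinusoids, 15 in sinusoids, 9 for arteries against sinusoids and 2 for distance. With counts summed per slide and niche edgeR called 12 in endosteum, 9 in low sinusoids (0 higher) and 22 over all niches. It then called 0 in sinusoids (391 at an unadjusted p under 0.05) and 0 for endosteum against sub-endosteum (402).

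Scaling changed the count in low sinusoids from 73 (57 higher, 16 lower) to 46 (33 and 13) with DESeq2 size factors and 48 (31 and 17) with TMMwsp. These moved the median of all genes for sinusoids against low sinusoids by 0.10 and 0.12 on the log2 scale, and DESeq2 itself by 0.11. In low sinusoids TMMwsp moved it by -0.13. With the most abundant genes left out, arteries against sinusoids gave 8 genes (2 higher, 6 lower). Adding the 2 outlier regions gave 28 in low sinusoids, 2 for endosteum against sub-endosteum and 54 over all niches. Area as a covariate gave 32 in arteries, 44 in low sinusoids and 60 over all niches. The share of reads outside exons as a covariate gave 41 in arteries, 54 in endosteum, 27 in low sinusoids and 13 for arteries against sinusoids. The number of coding genes as a covariate gave 47 in arteries, 7 in endosteum, 2 in sinusoids and 3 for arteries against sinusoids. Without the 2 libraries there were 4 in low sinusoids and 10 for arteries against sinusoids. Without the region absent from the authors' table there were 2 in sinusoids.

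Leaving out 1 slide gave 13 to 32 genes in arteries (32 without slide 1), 16 to 30 in endosteum (16 without slide 1) and 0 to 1 in sub-endosteum (1 without slide 1). In low sinusoids it gave 2 to 177, with 36, 124, 2, 20, 177 and 32 without slides 1, 4, 6, 8, 10 and 14. In sinusoids it gave 0 to 10, with 5, 3, 2, 10, 3, 2, 4, 0 and 0 without slides 3, 4, 5, 6, 7, 8, 10, 13 and 14. Arteries against sinusoids gave 3 to 16, with 16, 3, 3, 10, 9, 9 and 3 without slides 4, 6, 7, 8, 10, 13 and 15. Sinusoids against low sinusoids gave 0 to 22, with 0, 1, 1, 1, 22, 1, 5 and 1 without slides 1, 5, 6, 8, 10, 13, 14 and 15. Endosteum against sub-endosteum gave 1 to 3, with 2, 2 and 3 without slides 6, 8 and 14. The test over all niches gave 34 to 141 (34 without slide 6) and distance 0 to 0. Leaving out 1 region gave 12 to 30 in arteries (12 without arteries 39 or 69, 30 without arteries 8) and 18 to 30 in endosteum (18 and 19 without endosteum 23 and 37). It gave 7 to 124 in low sinusoids (7, 8 and 124 without low sinusoids 29, 6 and 55), 1 to 2 in sinusoids (2 without sinusoids 43 or 46) and 0 in sub-endosteum. Rgs5, Ltbp4, Carmn, Fbln2 and Cavin1 in arteries, Col1a1, Col1a2, Sparc and Cpe in endosteum and Cavin1 and Cd226 in low sinusoids were called under every setting in which they were tested.

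With an estimated correlation 2 lists were called in arteries, 2 in endosteum, 1 in low sinusoids, 0 in sinusoids and 0 in sub-endosteum, against 9, 7, 12, 4 and 8 with the preset one. Fry called 6 in arteries, 7 in endosteum, 8 in low sinusoids, 1 in sinusoids and 0 in sub-endosteum. Without the slide term 7 were called in sinusoids, and with the outlier regions 4 in sub-endosteum. Leaving out 1 slide gave 8 to 10 lists in arteries, 5 to 8 in endosteum, 9 to 15 in low sinusoids, 3 to 5 in sinusoids and 5 to 9 in sub-endosteum (5 without slide 10). The skeletal muscle list in low sinusoids was not called without the slide term, with summed counts, without the 2 libraries or with either covariate for library makeup.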

Other observations

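The covariates, the 2 libraries left out and the counts of detected genes in single regions below were chosen after the data were seen; the relabelings and the pairs were planned. Some lists not described above differed between pairs of niches. In arteries against sinusoids 4 lists were lower by camera: erythroid genes (1 of 29 positive, median -0.57, adjusted p = 0.00198), late neutrophil granule genes (2 of 23, -0.67, 0.00232), proliferation genes (1 of 28, -0.55, 0.000752) and megakaryocyte and platelet genes (6 of 24, -0.30, 0.016). Niche cytokine and ligand genes were higher (21 of 34, 0.11, 0.0043). With an estimated correlation, the one other setting of the pairs, 0 of these 5 were called (adjusted p = 0.832, 0.696, 0.678, 0.902 and 0.538). In sinusoids against low sinusoids, fibroblast and matrix genes (15 of 22 positive, median 0.93, adjusted p = 0.0173) and monocyte and macrophage genes (21 of 27, 0.81, 0.016) were higher. T and NK cell genes were called lower (adjusted p = 0.0383) although 7 of 14 were positive and the median was 0.09. An estimated correlation gave adjusted p of 0.454, 0.696 and 0.454. In endosteum against sub-endosteum all 16 early neutrophil granule genes were positive (median 0.61, adjusted p = 0.00626). Of 9 mitochondrially encoded genes 1 was positive (median -0.20, adjusted p = 0.0383). Here an estimated correlation gave adjusted p of 0.678 and 0.736.

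The regions most alike were sub-endosteum 14 and sinusoids 15, which lie on the same slide. Their Pearson correlation across coding genes on the log2 scale was 0.945, where genes are not independent replicates. With 13809 and 14827 coding genes with a count, each was the highest of its niche. The median over pairs of regions was 0.546 within niche and slide, 0.550 within niche between slides, 0.626 between niches on a slide and 0.589 between both. How far these correlations follow depth and the number of genes with a count was not tested. The authors' region table holds 74 regions, lists sub-endosteum 31, which the labels mark as an outlier, and does not list endosteum 30, which they mark as passing. It calls the 14 sinusoid regions high sinusoids.

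How often other groupings gave as many calls was counted by exchanging niche labels within slides, with the dispersions of the real grouping kept. For the number of genes called, no other grouping reached the 73 of low sinusoids (1 of 25 groupings with the real one included, highest other 47). This passes the bound set in advance, but 1 of 25 is the lowest share that 25 groupings can give. Many results were tested in this way without correction, so chance is not excluded. The count of 73 rests on few libraries. It was 7 without low sinusoids 29, 8 without low sinusoids 6 and 2 without slide 6, all below 47. The groupings were not repeated without these libraries. For arteries (19 genes, 4 of 25, highest other 83) and endosteum (29, 3 of 25, 81) other groupings gave as many calls. They also did for sinusoids (1, 16 of 25, 85) and for all niches together (95, 4 of 25, 182), so chance was not excluded there. This concerns the number of genes, and single genes were not followed through the groupings. Rgs5 in arteries and Col1a1 and Col1a2 in endosteum were called under all settings and leave-outs run. Those fits kept the real niche labels, so they do not test chance for these genes. In sub-endosteum edgeR called 0 (627 at an unadjusted p under 0.05, 116 by DESeq2), which all 25 of 25 groupings reach by construction, so nothing follows from it; the highest other gave 276. For the pairs chance was not excluded either. Arteries against sinusoids gave 5 genes (4 of 33, highest other 13). Sinusoids against low sinusoids gave 3 (5 of 33, 30) and endosteum against sub-endosteum 1 (3 of 33, 3). Some groupings thus called several times the real count. This may reflect a structure of the regions other than their niche, the dispersions kept from the real grouping, or single libraries with many sparse genes. Which of these holds was not tested. With the preset correlation, other groupings called as many lists as the real one in sinusoids (4 lists, 8 of 25, highest other 8). None did in arteries (9 lists, 1 of 25, 7), endosteum (7, 1 of 25, 6), low sinusoids (12, 1 of 25, 6) and sub-endosteum (8, 1 of 25, 7). Here too 1 of 25 passes the bound but is the lowest share possible, so chance is not excluded. The margin was small in endosteum, with 5 lists without slide 3 or 6, and in sub-endosteum, with 5 without slide 10, 6 without slide 3 or 6 and 4 with the outlier regions. With an estimated correlation 2, 2, 1 and 0 lists were called in these 4 niches, and fry called 0 in sub-endosteum. For distance among arteries edgeR called 0 genes (18 at an unadjusted p under 0.05, 1 by DESeq2), which all 100 of 100 permutations reach by construction, so nothing follows from it either; the highest other gave 10.

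The first pattern is the 57 sparse genes called higher in low sinusoids, which differ from the vessel genes that were lower there. One candidate explanation is a single library: without low sinusoids 29, 2 of the 57 were still called. Another is reads outside exons, such as unspliced or genomic sequence, which could give a low signal across many genes. With their share as a covariate 16 of the 57 were still called, and arteries 45, the other library with over 80% of such reads, had a count for 54 of them. Both remain open. Low sinusoids 6, which had a count for 52 of the genes, had 50.9% of unique reads outside exons, so that share does not mark it. A biological difference in these 2 regions was not tested.

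The second pattern is the rise of neutrophil granule genes at the endosteum, with a median log2 fold change of 1.17 for the late list. Richer libraries at the endosteum may account for part of it: with the number of detected coding genes as a covariate the median was 0.72, and the list was still called. The list kept its call in all 12 fits that left out 1 endosteum region, with a lowest median of 0.86 (without endosteum 37). Against the sub-endosteum alone the median was 0.77, so that fewer marrow cells in the artery regions may also contribute. None of the 3 tests went past the bounds set in advance, and a larger share of granulocytes along the bone stays open as an untested biological explanation.

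The third pattern is the lower level of stromal, vessel, megakaryocyte and other lists in low sinusoids, 10 lists in all. Of the 10 lists, 9 were still called with the number of detected genes as a covariate, and 9 without the libraries with most reads outside exons. Both tests used the preset correlation, under which exchanged niche labels gave up to 6 lists in low sinusoids. Among single genes, Cavin1 and Cd226 kept their calls without those libraries, while Sparc, Actb, Pros1 and Gucy1b1 did not. Library makeup is therefore not excluded as a part of this pattern. As these areas were chosen for few sinusoids, a lower share of vessel, perivascular and megakaryocyte RNA in them is a hypothesis consistent with these 2 tests, found and tested on the same data. How much of it follows from the choice of areas cannot be separated here from other differences between the regions; of the 10 lists, 1 (CAR cell genes) was also called with an estimated correlation.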
